A study of Mus musculus with 6 samples.

How the data were processed

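Bulk RNA sequencing was done on interscapular brown adipose tissue of C57BL/6J mice kept at 4 degrees C for 10 days, per the labels. The control group had loxP-flanked Mafb alleles, and the Mafb_KO group carried the same alleles with a Cre recombinase expressed from the lysozyme 2 (Lyz2, LysM) locus, which is active in macrophages and other myeloid cells. Each group had 3 libraries, and the mice were littermates aged 8 weeks at grouping, per the series' design text. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

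For each library the authors deposited a table of gene symbols with a count and a TPM value, which is scaled for gene length and depth. Per the file headers, the first value column holds the count of each gene. The counts were whole numbers, were not normalized, and differed in total between libraries. Per the file headers, the other column holds TPM, which had the same sum in every library. The deposited TPM equalled the counts divided by a fixed length per gene: over 11641 genes with at least 20 counts in every library, the largest ratio between libraries of the implied lengths was 1. Per the submitters' processing notes, STAR 2.6.1a, edgeR and the mm10 build were used, with no role given for each tool. Paired-end reads were aligned with STAR to 1 alignment file per sample, per the labels. The counting tool, its treatment of strand and of reads shared between genes, and the annotation are not given in the sources used here. Reads from paralogues, overlapping genes and antisense partners therefore could not be told apart, and genes with near-identical copies (Lyz1 and Lyz2, the H2-Q genes, the Mup and immunoglobulin families) are uncertain. Every table listed 20050 genes, each with at least 1 count in some library. Coordinates were taken from GENCODE release M21 of the mouse, on GRCm38, the same assembly as mm10, and 97.5% of listed symbols were found there.

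Genes were tested with edgeR 4.0.16 in R 4.3.3. Counts were filtered with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), scaled with TMM factors, and tested with the quasi-likelihood test of Mafb_KO against control with no covariate. The 13659 genes kept held 99.9% of all counts. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Values per library are CPM, counts relative to TMM-scaled library sizes, and errors are standard deviations over the libraries of a group or standard errors of the log2 fold change from the model. Positive log2 fold changes mean higher values in Mafb_KO. Exact permutation tests of 3 against 3 libraries cannot go below a two-sided p of 0.1, so they were not used to call differences. The largest chi-square per degree of freedom between libraries of a group was 40.6 and the smallest 13.6, so no library was a duplicate of another.

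A total of 31 gene lists (cell types, pathways and signs of sample quality) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and 26 of them had the 5 measured members required. Camera with an estimated correlation and fry were run beside it. Within each list, p-values of single genes were also adjusted over the list alone. Some lists share members. Among them, Nr4a1 of the monocyte list, Egr2 of the Schwann cell list and Atf3 of the stress list are also on the immediate early list. A list score is the mean over its members of log2 CPM centred on each gene's mean over the 6 libraries. Genes were named in the text by a rule. It took Mafb, Lyz2, Ucp1, Ppargc1a, Dio2, Th, Ngf and Il6 in any case. It also took up to 12 genes per direction past the adjusted threshold with no overlap between groups and a mean of at least 1 CPM in the higher group, ranked by log2 fold change. Where fewer than 5 passed in a direction, those with the smallest p filled up to 5 and are said not to pass, and clone-type symbols were skipped. From each list it took the members that passed over all genes or over the list alone, at most 4 by smallest p, and where none passed the 2 with the smallest p as values. Genes named outside this rule are said to have been chosen after their values were seen. The groups, the main test, the lists, the naming rule and the alternatives were chosen before the data were examined, except where stated.

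The alternatives were other scalings (DESeq2 size factors, upper quartile), no filter, a filter of at least 1 CPM in 3 libraries, leaving out the 10 most abundant genes, DESeq2 1.42.0, limma voom, the replicate number as a block, a minimum log2 fold of 1, and leaving out each of the 6 libraries in turn. After the data were seen, a fit was added in which a smooth trend of each library on gene length (from the ratio of counts to TPM) was removed as an offset. The procedure was tested on simulated counts for Mafb_KO against control, drawn from the libraries' means and sizes for 13548 genes, with 200 genes changed. It recovered 44% of genes changed by a fold of 1.5, 74% at a fold of 2, 96% at a fold of 4 and 96% at a fold of 8, with 14 false among 169 calls. In a simulation of the same kind, a shift of 0.5 (log2) in the pan-macrophage list was called and 0 other lists were. Genes were drawn independently in each simulation. The list result thus does not test list calls where genes vary together, and the shares of genes recovered need not hold in the real libraries. In the real libraries the estimated correlation within a list reached 0.95 (skeletal muscle). Plots were drawn with matplotlib 3.10.9.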

Results

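Gene expression was measured in interscapular brown fat, the main heat-producing fat depot of the mouse, after 10 days in the cold. The tissue came from mice with intact floxed Mafb (control, 3 libraries) and mice in which Cre from the Lyz2 locus deletes Mafb, a transcription factor of macrophages, in myeloid cells (Mafb_KO, 3 libraries). Total counts ran from 12499326 to 18270814 in the control libraries and from 12012489 to 15548734 in the Mafb_KO libraries. Mitochondrial ribosomal RNA took 16.9%, 24.0% and 25.2% of the counts in control libraries 1 to 3 and 18.3%, 15.1% and 18.5% in the Mafb_KO libraries. Rn45s, the precursor of cytosolic ribosomal RNA, took 2.61%, 2.00% and 2.20% in the controls. It took 3.15%, 3.35% and 2.86% in Mafb_KO, so the groups did not overlap in this share. Log2 CPM correlated between libraries at 0.971 to 0.988 across genes, which are not independent replicates. The comparison asks, per the series' title, how loss of macrophage Mafb affects the adaptation of brown fat to cold. No group carried Cre without floxed Mafb. Effects of Cre, or of its insertion at Lyz2, therefore cannot be told apart from those of Mafb loss.

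Mafb itself (chromosome 2, 160363703 to 160367065, GRCm38, 1 exon) was lower in the Mafb_KO tissue, at 7.45 ± 2.07 CPM against 11.4 ± 1.56 CPM in the controls (SD, n = 3 each). Its counts were 160, 161 and 147 in the control libraries and 123, 82 and 100 in the Mafb_KO libraries. The log2 fold change was -0.62 (SE 0.19), and it did not pass over all genes (edgeR adjusted p = 0.310). Mafb_KO libraries 2 and 3 lay below all 3 controls in CPM, and Mafb_KO library 1 lay within the control range. The tissue also holds cells without Cre, so whole-tissue counts do not give the extent of deletion in macrophages. Lyz2 (chromosome 10, 117277331 to 117282321), the macrophage lysozyme gene that carries Cre, had a log2 fold change of 0.15 (SE 0.20, edgeR adjusted p = 0.821), and its direction turned without Mafb_KO library 2 (-0.05). Only the Mafb_KO group has Cre at this locus, so Lyz2 counts cannot show whether myeloid content was the same in the groups. Lyz1, its neighbouring paralogue, chosen after its values were seen, had a log2 fold change of 1.01 (SE 0.28, edgeR adjusted p = 0.279), and reads may be shared between the copies.

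Across the tissue, no gene passed over all genes, and those with the smallest p-values are given as values. Npr3, the clearance receptor of natriuretic peptides, stood at 125 ± 11.2 CPM in Mafb_KO and 68.0 ± 8.35 CPM in the controls (SD, n = 3 each), a log2 fold change of 0.88 (SE 0.10). Ckb, the brain-type creatine kinase that takes part in creatine cycling, stood at 22.5 ± 1.38 CPM and 38.7 ± 3.20 CPM (SD, n = 3 each), a log2 fold change of -0.78 (SE 0.09). Both had an edgeR adjusted p of 0.0981, and their groups did not overlap. The other genes on the higher side were Tmem45b (log2 fold change 1.28), the prostaglandin D2 synthase Ptgds (1.43), the kinesin Kifc3 (0.52) and Ahcyl2 (0.44). Those on the lower side were the cilia gene Ttc25 (-1.05), Tmem256 (-0.67), the endoplasmic reticulum peroxidase Gpx8 (-0.74) and the mitochondrial cysteinyl-tRNA synthetase Cars2 (-0.39). These 8 genes did not pass either (edgeR adjusted p from 0.115 to 0.151).

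In counts, edgeR called 0 of 13659 genes, with 1597 at an unadjusted p under 0.05 (762 higher and 835 lower) where chance gives 683. DESeq2 called 140 genes (67 higher and 73 lower) and limma voom 0. Without a filter on low counts, edgeR called 41 genes (28 higher and 13 lower). In 2419 genes (17.7%) the groups did not overlap, against 10% by chance. The biological coefficient of variation was 12.1%. Leaving out 1 library gave 0 to 4 calls: Ttc25 without control library 2, Iigp1 and Net1 without Mafb_KO library 1, and Hp, Lilr4b, Ptgds and Tmem45b without Mafb_KO library 3. Genes named here outside the naming rule were chosen after their values were seen.

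Genes of the thermogenic program of brown adipocytes were lower as a group in Mafb_KO, by small amounts. Ucp1, the mitochondrial uncoupling protein that makes heat, stood at 3907 ± 499 CPM against 5436 ± 308 CPM in the controls (SD, n = 3 each), with no overlap between groups. Of the 22 listed genes, 17 had lower and 5 higher values, with a median log2 fold change of -0.13 (camera adjusted p = 0.000223). The call was lost with an estimated correlation (adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone, 4 genes fell, 0 rose and 18 did not pass. Over all genes edgeR called 0 of them, with 7 of the list at an unadjusted p under 0.05, and DESeq2 called the 4 (adjusted p from 0.000239 to 0.0331). These 4 were the cytochrome oxidase subunit Cox8b (-0.43, SE 0.10), Ucp1 (-0.48, SE 0.12), the potassium channel Kcnk3 (-0.34, SE 0.10) and the fatty acid elongase Elovl3 (-0.37, SE 0.11). Ppargc1a, the coactivator of mitochondrial genes, had a log2 fold change of -0.03 (SE 0.14), and Dio2, which activates thyroid hormone, had -0.49 (SE 0.31), which became -0.13 without control library 1, -0.25 without Mafb_KO library 1 and -0.83 without Mafb_KO library 3. Short genes of any kind tended to lower values in Mafb_KO, with a median log2 fold change of -0.12 in the shortest 10%. With that trend removed, Cox8b moved to -0.23 while Ucp1 (-0.45), Kcnk3 (-0.36) and Elovl3 (-0.36) stayed about as large, and 0 of the 4 passed over the list alone (adjusted p from 0.0588 to 0.115). Leaving out 1 library kept 0 to 3 of them.

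General adipocyte and mitochondrial genes were lower by a similar or smaller amount, and white fat genes were higher in part. The general adipocyte list had 11 of 14 genes lower (median -0.10, camera adjusted p = 0.0390, and adjusted p = 0.645 with an estimated correlation), with Adipoq, the adiponectin gene, at -0.22 and the lipid droplet gene Cidec at -0.22, neither passing. The mitochondrial respiratory chain list had 21 of 26 genes lower (median -0.07, camera adjusted p = 0.0197, and adjusted p = 0.809 with an estimated correlation), with Cox5b at -0.36 and Sdhd at -0.35, neither passing. The white adipocyte list had 5 of 7 genes higher (median 0.15, camera adjusted p = 0.00121, and adjusted p = 0.645 with an estimated correlation). In it, Npr3 and Lep, the leptin gene (log2 fold change 1.40, SE 0.40), rose when adjusted over the list alone, and Lep did not pass without control library 3 or Mafb_KO library 2. The respiratory chain call ended with the length trend removed (adjusted p = 0.457) and without control library 2 (0.173), control library 3 (0.0596), Mafb_KO library 1 (0.255) or Mafb_KO library 2 (0.0602). The general adipocyte call ended with the trend removed (0.0614), with upper quartile scaling (0.0501) and without control library 2 (0.10), control library 3 (0.0624) or Mafb_KO library 2 (0.151), and the white adipocyte call ended without Mafb_KO library 1 (0.449) and with limma voom (0.0739).

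**Figure D1:**
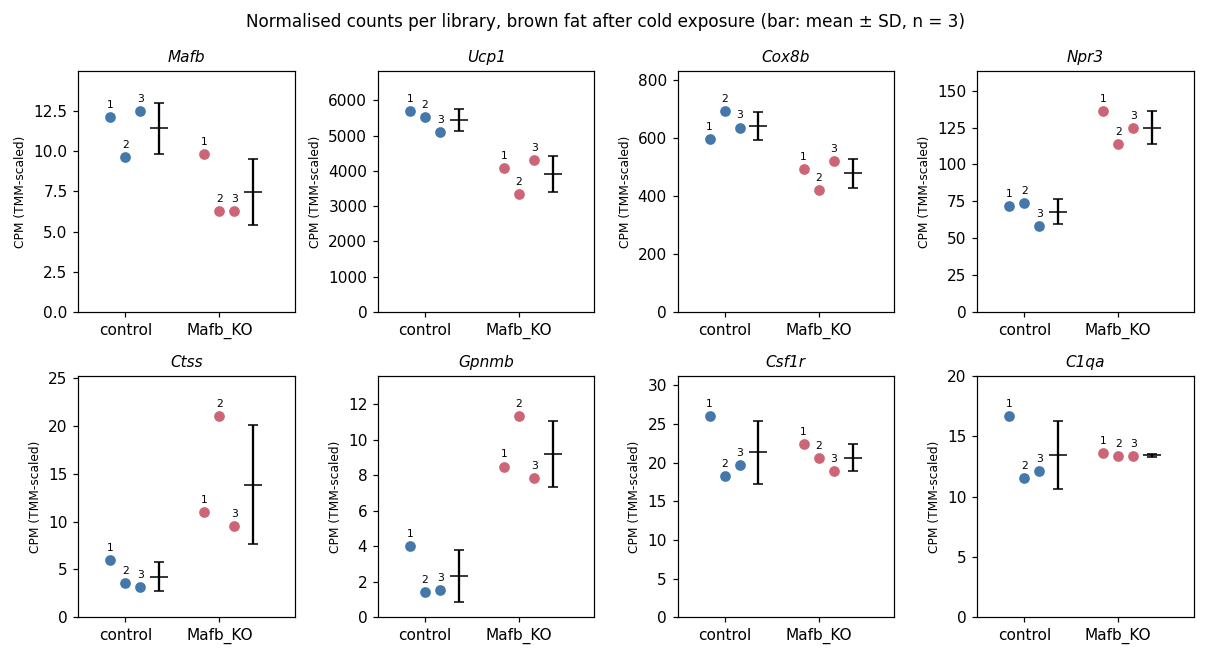
Normalised counts (CPM on TMM-scaled library sizes, linear axes from 0) of 8 genes in each library, with control in blue, Mafb_KO in red, replicate numbers above the points, and the mean ± SD (n = 3) as a black bar. Ucp1, Cox8b, Npr3, Ctss and Gpnmb do not overlap between groups, whereas Csf1r (log2 fold change -0.05) and C1qa (0.00) do.

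Several genes of phagocytic and lipid-laden macrophages were higher in Mafb_KO, and the list of resident macrophage genes was not called. In the pan-macrophage list, 14 of 16 genes had higher values (median log2 fold change 0.52, camera adjusted p = 1.47e-08), a call lost with an estimated correlation (adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone, 6 genes rose, 0 fell and 10 did not pass. Over all genes edgeR called 0 of them, with 7 of the list at an unadjusted p under 0.05. Among the 6 were the lysosomal protein gene Laptm5 (0.61, SE 0.10), the pore-forming protein gene Mpeg1 (1.23, SE 0.23), the cathepsin gene Ctss (1.70, SE 0.34) and the NADPH oxidase subunit gene Cybb (0.93, SE 0.19). These 4 were called over all genes by DESeq2 (adjusted p from 5.40e-06 to 0.0275) and passed over the list alone in all 6 fits without 1 library, and Cd68 and Spi1, the other two, did not. Csf1r, the receptor for the macrophage growth factor, was at -0.05 (SE 0.14) and Adgre1, which encodes F4/80, at 0.12 (SE 0.16), both chosen after their values were seen.

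The lipid-associated macrophage list had 9 of 12 genes higher, with a median of 0.16 and a mean of 0.81 (camera adjusted p = 4.90e-06, and adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone, 5 of its genes rose and 7 did not pass. Over all genes edgeR called 0 of them, with 5 at an unadjusted p under 0.05, and DESeq2 called Gpnmb (adjusted p = 1.45e-06) and gave no adjusted p for Mmp12 and Itgax. Gpnmb, a glycoprotein of lysosome-rich macrophages, stood at 9.20 ± 1.86 CPM against 2.33 ± 1.46 CPM (SD, n = 3 each), a log2 fold change of 1.99 (SE 0.35). Mmp12, the macrophage elastase, was at 3.25 (SE 0.57), which became 4.02 without control library 1 (and Gpnmb 2.63), the integrin gene Itgax at 1.92 (SE 0.37) and the galectin gene Lgals3 at 1.60 (SE 0.43), which became 0.98 without Mafb_KO library 2. Capg was the remaining gene. Control counts were low for Mmp12 (15, 7 and 3, against 72, 120 and 43 in Mafb_KO) and Itgax (13, 11 and 4, against 36, 39 and 30). The size of their fold changes is therefore uncertain. Gpnmb, Mmp12 and Itgax passed over the list alone in all 6 fits without 1 library.

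Tissue-resident macrophage genes were lower in 10 of 16 cases (median -0.04, camera adjusted p = 0.153, not called), and the list was called lower without control library 2 (adjusted p = 0.00742) or control library 3 (0.0351). Without control library 1 the list turned to higher and was not called (camera adjusted p = 0.788). That library had a list score of 0.37, against -0.12 and -0.08 in the other controls. Selenop, the plasma selenoprotein gene, fell when adjusted over the list alone (-0.26, SE 0.06), a call absent from all 6 fits without 1 library. The list of complement C1q and uptake of apoptotic cells, which holds known targets of MAFB, was not called (16 genes, median 0.05, camera adjusted p = 0.158), except without control library 1 (adjusted p = 0.00383, higher). C1qa, C1qb and C1qc, chosen after their values were seen, had log2 fold changes of 0.00 (SE 0.14), 0.05 (SE 0.23) and 0.06 (SE 0.22). In that list Mfge8, which bridges phagocytes to dying cells (0.41, SE 0.08), and the integrin gene Itgb5 (0.30, SE 0.08) rose when adjusted over the list alone. Leaving out 1 library kept 0 to 2 of those calls.

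**Figure D2:**
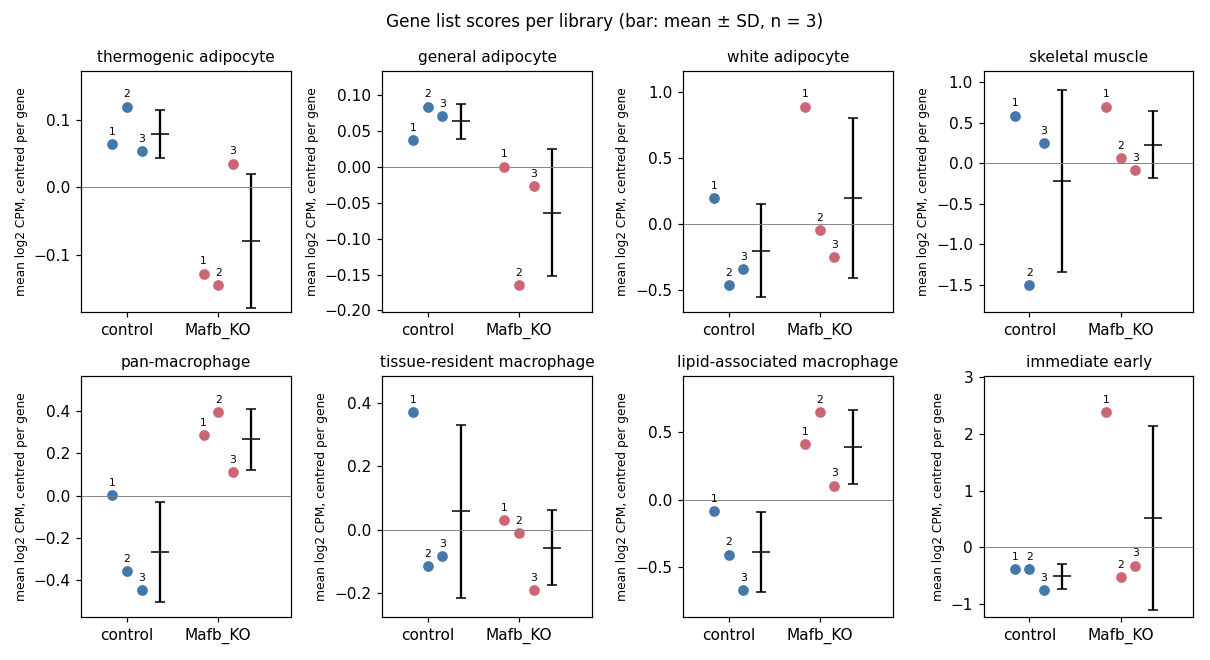
Scores of 8 gene lists in each library (mean over members of log2 CPM centred per gene, a separate linear axis per list), with control in blue, Mafb_KO in red, replicate numbers above the points, and the mean ± SD (n = 3) as a black bar. Pan-macrophage scores are 0.00, -0.35 and -0.45 in the controls and 0.29, 0.40 and 0.11 in Mafb_KO, while the immediate early score of 2.39 in Mafb_KO library 1 stands far above the other libraries.

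Genes of sympathetic nerves, which drive heat production through noradrenaline, had few counts in tissue RNA, and no difference was found in them. Summed over 17 genes of the list, they stood at 5.61 ± 0.306 CPM in Mafb_KO and 6.23 ± 0.943 CPM in the controls (SD, n = 3 each, exact permutation p = 0.400). That test cannot go below 0.1, so it could not have called a difference. Only 2 of 17 sympathetic neuron genes passed the count filter, Slc18a2 (log2 fold change 0.45, SE 0.26) and Stmn2 (-0.29, SE 0.25), and neither passed a test. Th, the rate-limiting enzyme of noradrenaline synthesis, had 7, 0 and 4 counts in the controls and 1, 0 and 2 in Mafb_KO, too few to tell a difference. Whether depth or scarce transcripts limits these genes was not tested, and nerve density was not measured. Ngf, the nerve growth factor, had 18, 14 and 4 counts and 12, 6 and 16 counts, a log2 fold change of -0.08 (SE 0.49). Its direction turned with limma voom (0.03) and without control library 1 (0.39) or Mafb_KO library 2 (0.19). The neurotrophic and axon guidance list was not called (14 genes, 9 higher, median 0.03, camera adjusted p = 0.699). Nrg4, a growth factor secreted by brown fat, fell when adjusted over the list alone (-0.29, SE 0.07), a call kept only without Mafb_KO library 3 among the fits that left out 1 library. Schwann cell genes (13 genes, median 0.08, camera adjusted p = 0.0897) and noradrenaline clearance genes (5 genes, median 0.00, camera adjusted p = 0.699) were not called. The Schwann cell list was called higher without a filter (adjusted p = 0.0140) and without control library 1 (0.0122), control library 3 (0.00466) or Mafb_KO library 3 (0.0163). In these lists Scn7a (0.56), Mal (1.09), Maoa (0.31) and Slc18a2 had the smallest p-values and did not pass, and Mal became 1.96 without control library 1.

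Most inflammatory cytokine genes were near the detection floor, and some other immune genes were higher in Mafb_KO. Of 21 cytokine genes 4 passed the filter, led by Socs3 (1.30, SE 0.77) and Cxcl10 (0.76, SE 0.47), and none passed a test. Socs3 became -0.37 without Mafb_KO library 1, and Cxcl10 became 0.12 without Mafb_KO library 2. Il6 had 0, 1 and 0 counts in the controls and 4, 0 and 0 in Mafb_KO. The immunoglobulin genes Ighm (1.45, SE 0.22) and Igkc (1.73, SE 0.57) rose when adjusted over the list of 4 measured B and plasma cell genes alone. Ighm kept this in all 6 fits without 1 library. Igkc kept it only without control library 2 or Mafb_KO library 3, and at 0.875 CPM in Mafb_KO library 3 it lay below all 3 controls. The monocyte list was higher (6 genes, median 0.82, camera adjusted p = 0.00906, and adjusted p = 0.543 with an estimated correlation), and only Hp, haptoglobin, which adipocytes also make, rose when adjusted over the list alone (0.92, SE 0.15). The call of the monocyte list ended without Mafb_KO library 1 (adjusted p = 0.126) and with limma voom (0.104). That library had the highest monocyte score (0.78), and Nr4a1 is also on the immediate early list, which was high in the same library. The neutrophil genes Csf3r (2.15) and S100a9 (2.03) did not pass, and S100a9 became 0.06 and Csf3r 0.81 without Mafb_KO library 1. No gene of the T and NK cell list passed the filter (0 of 17).

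All 17 measured interferon response genes had a higher fitted value in Mafb_KO (median 0.58, camera adjusted p = 2.09e-06, and adjusted p = 0.645 with an estimated correlation). Mafb_KO library 2 stood apart, with a list score of 0.86 against -0.08 and -0.04 in the other Mafb_KO libraries and 0.01, -0.31 and -0.44 in the controls, and without it the camera adjusted p was 0.0264. None passed over the list alone, and the guanylate-binding protein genes Gbp2 (0.64, SE 0.18) and Gbp3 (0.55, SE 0.15) had the smallest p-values. Immediate early genes, which respond within minutes to stimulation, were high in Mafb_KO library 1: Fos had 1949 counts there and 17 to 32 in the other libraries, and Egr1 had 1797 and 60 to 140. Their list was higher by camera (11 genes, median 1.61, camera adjusted p = 0.000156, and adjusted p = 0.645 with an estimated correlation), and the call ended without that library (adjusted p = 0.449). Skeletal muscle genes were higher in 15 of 17 cases (median 0.20, camera adjusted p = 0.0361, and adjusted p = 0.809 with an estimated correlation). Control library 2 had little muscle RNA, with Ttn, the sarcomere protein titin, at 0.154% of its counts and 0.486% to 0.845% in the others. Without control library 2 the muscle list turned lower (camera adjusted p = 0.0315). It was not called without Mafb_KO library 1 (0.554) or with upper quartile scaling (0.0505). Ttn (0.57, SE 0.42) and the myosin gene Myh7 (0.57, SE 0.54) had its smallest p-values and did not pass.

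The remaining lists were not called by camera. Their adjusted p-values were 0.542 for UCP1-independent energy cycling, 0.542 for fatty acid oxidation, 0.736 for de novo lipogenesis, 0.158 for glycolysis and 0.494 for the circadian clock. They were 0.158 for endoplasmic reticulum and integrated stress, 0.127 for endothelium, 0.972 for pericyte and smooth muscle, 0.132 for fibroblast and extracellular matrix, 0.699 for mast cell, eosinophil and type 2, and 0.699 for cell cycle. Without control library 1, calls arose for glycolysis (lower, 0.0447), the clock (higher, 0.0170), stress (higher, 0.0138) and fibroblast genes (higher, 3.47e-07). Calls also arose for stress genes without Mafb_KO library 1 (0.0394) or a filter (0.0424), for endothelium without Mafb_KO library 1 (lower, 0.00301), and for fibroblast genes without Mafb_KO library 2 (0.0125) or 3 (0.0424). Adjusted over the list alone, Ckb, the glycolytic enzyme gene Pfkp (-0.43) and the chaperone gene Hsp90b1 (-0.29) fell. Adjusted over the list alone, the collagen cross-linking enzyme gene Lox (0.53), the stress pseudokinase gene Trib3 (0.88) and the clock gene Per1 (0.69) rose. Ckb and Lox kept this in all 6 fits without 1 library, and Pfkp, Hsp90b1, Trib3 and Per1 did not. Members with the smallest p-values that did not pass were Cpt1a (0.35), Ehhadh (-0.32), Elovl5 (-0.24), Fads1 (0.31), Emcn (-0.32), Kdr (-0.21), Notch3 (0.22), Tagln (-0.30), Cpa3 (0.23), Il33 (0.31), Tyms (0.46) and Mcm2 (0.30).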

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

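The fit with the length trend removed was chosen after the data were seen, and the other alternatives were planned. Over 70 named genes and all alternatives, 980 of 1044 values kept their direction and side of the threshold, 54 passed where the reported value did not, and 10 turned direction. Of 352 values for the 22 lists outside the main question, 283 kept both, 33 lost the call, 16 gained one and 20 turned direction. No scaling moved the median log2 fold over all genes by more than 0.02. Except where stated, the cause of a change was not tested.

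Against 0 genes with edgeR, no filter gave 41 (28 higher, 13 lower), of 20050 tested. DESeq2 gave 140 (67 higher, 73 lower), with 10496 genes left without an adjusted p, and limma voom, the other scalings and filters and the length fit gave 0. Fits that left out 1 library gave 0 to 4 genes (0 to 4 higher, 0 to 1 lower). A minimum log2 fold of 1 left 0, and the pseudocount alternative did not apply to counts. With the replicate number as a block, 10 genes were called (6 higher, 4 lower). Same-numbered libraries deviated together at correlations across genes of 0.24, 0.13 and -0.04, so the numbers were not taken to pair the samples, and libraries did not all correlate best with their own number. Of the lists, the block added a call for fibroblast genes (higher, adjusted p = 0.0211) and changed no other call.

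Of 10 lists called by camera, 0 were called with an estimated correlation and 0 with fry, and fits without 1 library called 7 to 17. Adjusted p-values of the thermogenic and pan-macrophage lists were both 0.543 with an estimated correlation and both 0.370 with fry. They stayed below 0.05 in the other alternatives run for lists, which leave out DESeq2 and the minimum fold, at up to 0.00741 for the thermogenic list and 4.55e-05 for the pan-macrophage list. Without a filter, lists then large enough to test gave camera adjusted p = 0.452 for sympathetic neuron, 0.00352 for inflammatory cytokine (higher), 0.0745 for neutrophil, 0.000175 for T and NK cell (higher) and 1.82e-07 for B and plasma cell (higher). Summed cytokine counts were 477 in Mafb_KO library 1 and 137 to 214 in the other libraries, and those of T and NK cells 210 in Mafb_KO library 2 and 36 to 98 in the others.

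Uncalled lists turned direction without a filter (adjusted p = 0.914 for the neurotrophic list, 0.911 for the mast cell list), with limma voom (0.975 for pericytes) and with fry (0.962 for pericytes), and Ngf turned with limma voom (log2 fold 0.026). Without 1 library, adjusted p-values ran as follows for lists that turned or crossed the threshold. They were 0.336 to 0.981 for fatty acid oxidation, 0.151 to 0.848 for de novo lipogenesis, 0.191 to 0.908 for neurotrophic factors and 0.488 to 0.890 for noradrenaline clearance. They were 0.00742 to 0.788 for resident macrophages, 0.00383 to 0.625 for C1q and uptake, 0.135 to 0.959 for mast cells and 0.00301 to 0.732 for endothelium. They were 0.282 to 0.912 for pericytes, 3.47e-07 to 0.988 for fibroblasts, 2.73e-06 to 0.554 for skeletal muscle and 0.135 to 0.774 for cell cycle. They were 0.00466 to 0.530 for Schwann cells, 0.0447 to 0.571 for glycolysis, 0.0138 to 0.181 for stress and 0.0170 to 0.777 for the clock. Of lists called with all libraries, the range was 0.000806 to 0.255 for the respiratory chain, up to 0.151 for general adipocytes, 7.14e-05 to 0.449 for white adipocytes, 6.98e-09 to 0.126 for monocytes and 1.26e-13 to 0.449 for immediate early genes. Log2 folds without 1 library ran from -0.046 to 0.35 for Lyz2, -0.15 to 0.14 for Ppargc1a, -0.41 to 0.39 for Ngf, -0.37 to 1.76 for Socs3, -0.22 to 5.45 for Fos and -0.034 to 3.45 for Egr1. The negative values of Socs3, Fos and Egr1 came without Mafb_KO library 1, which held their high counts.

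Adjusted over the list alone, the length fit kept 0 of 4 thermogenic genes (3 of them, Ucp1, Kcnk3 and Elovl3, with log2 folds about as large, at -0.45, -0.36 and -0.36), 6 of 6 pan-macrophage genes and 5 of 5 lipid-associated genes. Without 1 library, 0 to 3, 4 to 6 and 3 to 5 of these were kept. Few counts per library limit what can be said of Th, Il6 and most cytokine and neuronal genes.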

Other observations

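The tests of families, single genes and explanations in this part and the fit with the length trend removed were chosen after the results were seen, whereas the fits without 1 library and the other alternatives were planned. Of 22 measured genes with symbols starting H2-, most of them genes of the major histocompatibility complex, 20 had higher values in Mafb_KO. Their median log2 fold change was 0.48, with a camera adjusted p of 2.40e-09 over 10 families grouped by symbol, and adjusted p = 0.236 with an estimated correlation. All 10 guanylate-binding protein genes, which interferon induces and of which Gbp2 and Gbp3 are also in the interferon list, had higher values (median 0.55, camera adjusted p = 6.97e-09, and adjusted p = 0.236 with an estimated correlation). So did 6 of 7 leukocyte integrin and Fc receptor genes (median 1.01, camera adjusted p = 5.09e-06, and adjusted p = 0.236 with an estimated correlation). That group is not separate from the macrophage lists. It holds Itgax of the lipid-associated list, and its symbols cover Itgam and Fcgr1 of the pan-macrophage list. Nlrc5, the transactivator of class I genes, had a log2 fold change of 0.83, H2-Ab1 0.46 and the invariant chain gene Cd74 0.40, and none of them passed over all genes (edgeR adjusted p = 0.178, 0.276 and 0.295). H2-Q6 (1.17) and H2-Q7 (1.28) are near-identical copies whose reads may be shared, which leaves each uncertain on its own, and without any 1 library the family kept an adjusted p of at most 2.86e-06 (the length fit gave 1.03e-11).

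Further families were lower in Mafb_KO. Median log2 fold changes were -0.13 for 50 complex I genes (camera adjusted p = 2.28e-08), -0.10 for 77 mitochondrial ribosomal protein genes (5.83e-08) and -0.09 for 94 cytosolic ribosomal protein genes (3.90e-06). All were lost with an estimated correlation (adjusted p = 0.289 with an estimated correlation for each). With the length trend removed, adjusted p-values became 0.180, 0.00572 and 0.981, with medians of -0.02, -0.06 and 0.00. Heat shock and DnaJ genes had a median of -0.05 (camera adjusted p = 0.0121, and adjusted p = 0.289 with an estimated correlation), a call that held with the length trend removed (0.0227, median -0.05) and ended without 1 library in the least favourable fit (0.166). Proteasome (0.293), collagen (0.175) and mitochondrial carrier (0.587) genes were not called with all libraries, and the lowest adjusted p without 1 library was 0.0283, 0.000143 and 0.301. In the shortest 10% of genes, 263 were lower and 36 higher at an unadjusted p under 0.05, out of 1366 genes. Single genes outside these families, none past the edgeR threshold, were the adenylate cyclase gene Adcy3 (-0.95), the adipokine gene Apln (-0.88), the transcription factor gene Klf15 (-0.55), Fkbp5 (0.85), Txnip (0.53) and Fbxo32 (0.82). Within 5 Mb of Lyz2, 4 of 42 genes (9.52%) had an unadjusted p under 0.05, against 11.7% of all tested genes. In all 6 libraries Xist had at most 11 counts and Ddx3y at least 606.

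Pan-macrophage genes were higher in Mafb_KO without a matching rise of resident macrophage genes. A larger share of the same macrophages would raise both lists, but the score change of the pan-macrophage list exceeded that of the resident list by 0.65 (SE 0.06, log2). A trend with gene length as the whole cause is argued against by a median log2 fold of 0.59 with the trend removed, and a single library by a highest adjusted p of 3.18e-05 among the 6 fits without 1 library, although camera with an estimated correlation (adjusted p = 0.543) and fry (0.370) did not call the list. The 10 splits of the 6 libraries are too few for a share under 0.05: the real median was 0.52 and the highest of the other splits 0.47, so 1 split, the real one, was as large (for the lipid-associated list, 0.16 and 0.51, with 4 at least as large, the real one included). General leukocyte genes (Ptprc 1.06, Coro1a 1.29, Itgb2 1.07) and Ighm (1.45) also had higher values, and Laptm5, Ctss, Spi1 and Cybb are expressed by B cells too, so an altered state of macrophages that lost Mafb, or entry of other leukocytes, myeloid or lymphoid, may each underlie the pattern and stay open as untested hypotheses.

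Thermogenic genes were lower in Mafb_KO together with general adipocyte genes. The score change of the thermogenic list differed from that of the fatty acid oxidation list by -0.19 (SE 0.051, log2). Genes of fatty acid oxidation thus did not share the fall. That list may also take in RNA of other cells of the tissue, and Cpt1b is on both lists. The thermogenic change did not separate from those of de novo lipogenesis genes (-0.16, SE 0.11) or general adipocyte genes (-0.031, SE 0.060, log2). The lipogenesis score itself was flat, at a mean of 0.00079 (SD 0.11) in the controls and -0.00079 (SD 0.12) in Mafb_KO. The difference from fatty acid oxidation genes argues against an equally lower yield of all adipocyte transcripts, as far as that list reflects adipocytes. A fall shared with general adipocyte genes stays open. More muscle RNA stays open as a cause. Without control library 2, the one with least muscle RNA, the thermogenic score change was -0.14 (SE 0.057, log2). The muscle score change was then -0.19 (SE 0.29), an error too wide to set muscle RNA equal between groups. Mafb_KO libraries 1 and 2, lowest in thermogenic score (-0.13 and -0.14), had the highest Ttn shares (0.845% and 0.768%). In contrast, control library 1 had a muscle score of 0.59 and a thermogenic score of 0.064, and Mafb_KO library 2 had 0.065 and -0.14. A trend with gene length as the whole cause is argued against by a list median of -0.13 with the trend removed, at a camera adjusted p of 0.000244 (0.543 with an estimated correlation, 0.370 with fry and up to 0.00741 in the other alternatives run for lists). Of the 4 genes called over the list alone, the trend took part of Cox8b, from -0.43 (SE 0.10) to -0.23 (SE 0.09), while Ucp1 (-0.48 to -0.45, SE 0.12), Kcnk3 (-0.34 to -0.36, SE 0.10) and Elovl3 (-0.37 to -0.36, SE 0.11) stayed about as large, with their adjusted p moving past the threshold to between 0.0588 and 0.0635. With 10 splits no share under 0.05 can be had: 2 splits, the real one included, gave a median at least as large as the real 0.13 in size, the highest of the others being 0.14. An effect of genotype on the adipocytes themselves stays open.

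Immediate early genes were high in Mafb_KO library 1. A change shared by the Mafb_KO libraries is argued against by the other 2, whose mean score exceeded the control mean by 0.087 against a control SD of 0.22 (log2). Handling of 1 animal or tissue piece before lysis may give such a rise and cannot be told apart from a response of that animal, because no label records handling. The gap of this library to the nearest other one was 2.72 (log2).

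The splits of the 6 libraries into 3 and 3 were also counted for the whole comparison, and 10 splits cannot give a share under 0.05. The real split called 0 genes, as did all 10 splits (highest of the others 0). At an unadjusted p under 0.05 it gave 1597 genes and the highest of the others 1155, so 1 split, the real one, was as large. Camera with the preset correlation called 10 lists in the real split and up to 17 in the others, and 5 splits, the real one included, called at least as many. The split with 17 set control library 1 and Mafb_KO libraries 1 and 2 against the rest, a structure of the samples that crosses the genotypes. Those 3 libraries had the highest Ttn shares (0.651%, 0.845% and 0.768%) and the lowest shares of mitochondrial ribosomal RNA (16.9%, 18.3% and 15.1%). The same split gave the 1155 genes. It also gave the highest medians outside the real split for the pan-macrophage (0.47), thermogenic (0.14) and lipid-associated (0.51) lists.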
